A study of Octopus bimaculoides with 95 samples.

How the data were processed

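The series measured gene expression by RNA sequencing in the California octopus Octopus bimaculoides. It holds 95 libraries in 2 expression tables, 85 in the table of a sequencing plate and 10 in a second table. Per the labels' protocols, RNA from whole tissue was turned into cDNA, single neurons were taken to cDNA with no RNA extraction step, and libraries were made with NEBNext Ultra I or II kits. Per the series' design text, they were sequenced on HiSeq3000 or NextSeq500 instruments. The instrument and kit of each library are not given in the sources used here.

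The deposited values are TPM, transcripts scaled by length and by library total, and in each library they sum to a fixed total over all table entries, per the file headers and the values themselves. Per the submitters' processing notes, the tools used were Trimmomatic 0.32, STAR 2.3, featureCounts and edgeR 3.14.0; their roles, their settings and the genome build are not given in the sources used here. The plate table has 26467 entries: 92 ERCC spike-in RNAs, 18 sequences carrying a name of their own such as GNRH or VLPep3, and 26357 transcripts of 17527 gene IDs. The second table has 26466 entries, because 1 of the named sequences, NOS, has none there. Of the 17527 gene IDs, 15476 matched the RefSeq gene table of assembly ASM119413v2, which was used only for biotypes and for which genes neighbour each other. It gives those genes no symbol beyond the ID and no product name, so genes are reported by ID.

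From the deposited TPM, spike-ins were left out, each gene was represented by its transcript with the highest mean over the plate libraries, and values were rescaled to the original total over genes. The design fixed before the data were examined had named the TPM as deposited. The change was made after the tables had been looked at, because spike-ins took 1.27% to 94.1% of a library (median 40.3%), and before any gene was called. The unmodified scale and the mean over a gene's transcripts were run as alternatives. Among 4020 genes with several transcripts, the correlation between a gene's transcripts across libraries had a median of 0.9985 over the 2580 genes where it could be computed.

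TPM carries no depth, but the low values of each transcript were whole multiples of a step. Of plate values worth under 100 reads, 99.999% lay within 0.05 of a whole number of reads, and 99.77% of second-table values. Reads could be recovered this way for 14996 of 17545 genes of the plate table, which carried 52.2% to 97.7% of a library's TPM without spike-ins, and for 9881 of 17544 genes of the second, which carried 13.96% to 46.3%. Recovered reads are therefore lower bounds on depth, above all in the second table. The procedure was tested on simulated tables, where 99.9946% of values came back as the simulated read number on the plate design and 98.534% on the second. Simulated library totals came back in all 85 plate libraries and in 0 of 10 of the second table, at 0.971 to 0.982 of the true total. The median TPM of the genes with exactly 1 read was 0.0599 to 14.1 by plate library, with a median of 0.394 over libraries; single sequences can lie far from it, since the worth of a read depends on length. Recovered reads were used for depth and for an alternative test, not for the main results.

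Groups were taken from the tissue named in the labels. The plate table has 51 libraries of 21 neural tissues and 34 libraries of 25 non-neural tissues. Comparisons, tests, thresholds, the rule for named genes and most alternatives were fixed before the data were examined. The main test was limma with a mean-variance trend on log2(TPM + 1), with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Neural regions were compared in 1 fit over 45 libraries of the 15 neural tissues with 3 libraries, for genes at 1 TPM in at least 3 libraries. Non-neural tissues were compared in a fit over 15 libraries of 6 tissues, for genes at 1 TPM in at least 2. Neural and non-neural tissues were compared over 46 tissue means. Sides of a comparison were means over their tissues with equal weight, and the vertical lobe counted once among the central lobes. A region-enriched gene was higher in a region than in the mean of the other 10 and had its highest mean there. Tissue specificity used the index tau over 46 tissue means, at 0.9 or more with at least 10 TPM in the top tissue. Every difference is on the log2(TPM + 1) scale, which understates the change of low genes. Mean TPM can rest on 1 library: of 116 means of named genes at 5 TPM or more over at least 3 libraries, 61 moved by over 1.5 times without their highest library, and 18 by over 3 times. Tissues with 1 library and the second table were described by their values alone. Each table was scaled separately, so levels are set across the 2 tables as ranks or ranges, with no test.

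Named genes were chosen by the fixed rule. Its main part asked for product names and found none, so it reduced to at most 2 IDs per direction of a comparison, those with the largest difference and at least 5 TPM in the higher group, plus called sequences with a name of their own. For tissues with 1 library, up to 5 named sequences at 20 TPM or more with the largest excess were taken. All 31 gene lists and cell type marker lists fixed beforehand were patterns on product names. None matched a gene, so gene list tests were not run.

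Libraries were compared by Pearson's r of log2(TPM + 1) over 15094 genes. A library was set apart when its median r with tissues of the other class was above that with its own class, its own tissue left out of these medians, and its nearest among all other libraries, own tissue included, was of the other class. That rule was written after the correlations had been seen and uses the correlations alone. The main results keep every library under its label, and each count was run again without the 5 libraries set apart. No 2 libraries of a tissue held identical values. Over all pairs within tissues, the chi-square per degree of freedom of recovered reads was 7.75 or more, so none was counted as a repeat.

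Alternatives fixed beforehand were pseudocounts of 0.5 and 2, filters of 0 and 5 TPM, quantile and median ratio scaling, robust variance estimation, replicate numbers or letters as a block, fits on the compared groups alone, fits within a label style, merged subdivisions and each library left out. Chosen after seeing the data were the deposited scale, the mean over transcripts, limma's voom on recovered reads, log10 reads as a covariate, and the sets without libraries under 200000 reads or without those set apart. limma was tested on simulated data with known changes in each design. Computations used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.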

Results

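RNA was sequenced from the nervous system and other organs of Octopus bimaculoides, a cephalopod with a large, lobed brain. The plate table covers 21 neural tissues with 51 libraries. Of these, 15 tissues have 3 libraries each. The vertical lobe, a brain lobe of learning and memory, was divided into medial, left and right lateral, and left and right mediolateral parts. The other tissues with 3 libraries are the subvertical, inferior frontal, superior frontal, dorsal basal and anterior superior buccal lobes, the remaining basal and subfrontal lobes, the deep medulla and plexiform periphery of the optic lobe, which processes vision, the stellate ganglion, a motor ganglion of the mantle, and the arm cord close to the brachial crown. The remaining neural tissues have 1 library each, among them 3 parts of the subesophageal lobe. Of 25 non-neural tissues, the retina and both parts of the branchial heart have 3 libraries, both salivary glands and the chromatophores have 2, and the others have 1. The second table adds 5 whole tissue libraries and 5 single neurons. The labels do not state that libraries of a tissue come from separate animals, so p-values measure only the spread between libraries, which may in part be technical. Those for neural against non-neural tissues measure the spread between tissue means instead. There, parts of an organ, such as those of the vertical lobe, counted as separate tissues although they are related.

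The libraries differ widely in depth. Recovered reads over genes ranged from 35838 to 13464000 in the plate table, with a median of 913261 in neural and 1903600 in non-neural tissues, and 28 of the 85 libraries had fewer than 500000. Spike-in RNA took a median of 51.6% of the TPM in neural and 25.05% in non-neural libraries and exceeded 50% in 36 libraries. Between 4231 and 11740 genes reached 1 TPM, with a median of 8695. A single gene took 1.17% to 53.8% of a library. Second-table libraries had 6553 to 13526 genes at 1 TPM. Their 77603 to 3014770 recovered reads are lower bounds. Precision differs between libraries, as shown for GNRH below.

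**Figure D1:**
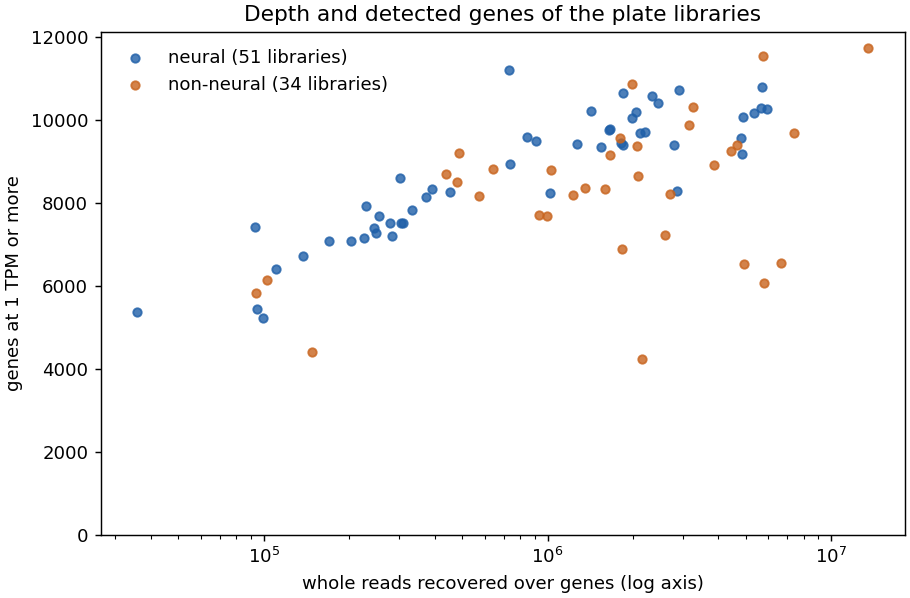
Genes at 1 TPM or more (vertical axis, 4231 to 11740) against recovered reads over genes (horizontal log axis, 35838 to 13464000). The 85 plate libraries are shown, 51 neural in blue and 34 non-neural in orange.

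Most libraries resembled tissues of their own class. The median over libraries of the correlation with neural tissues minus that with non-neural tissues was 0.0982 in neural and -0.0556 in non-neural libraries, and 41 of 46 tissues had their nearest tissue in their own class. The auricle lay nearest to the clear vessel of the systemic heart (r = 0.915), the superior buccal lobe to the remaining basal lobes (r = 0.943), the optic medulla to the periphery (r = 0.926), and the white body, a blood-forming organ, to blood (r = 0.847). These correlations run across genes, which are not independent replicates. By this measure 7 libraries lay on the side of the other class. Of these, the arm tip (0.00718) and the hectocotylus (0.00099) were nearest to each other, and the other 5 were nearest to a library of the other class. The library labelled chromatophores 1 was closer to neural tissues by 0.108 and nearest to a left mediolateral vertical lobe library (r = 0.937), while its correlation with chromatophores 2 was 0.668. The library labelled stellate ganglion 1 was closer to non-neural tissues (difference -0.114) and nearest to skin (r = 0.893), against at most 0.598 with the other stellate libraries. The library labelled right mediolateral vertical lobe 1 gave -0.0339 and lay nearest to the large sucker (r = 0.761); it had 99278 reads and 94.1% spike-in RNA. The libraries labelled optic gland and retina 3 were closer to neural tissues by 0.0581 and 0.0518, the latter with 102844 reads. These 5 are kept under their labels, and wherever they enter a comparison it was also run without them.

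**Figure D2:**
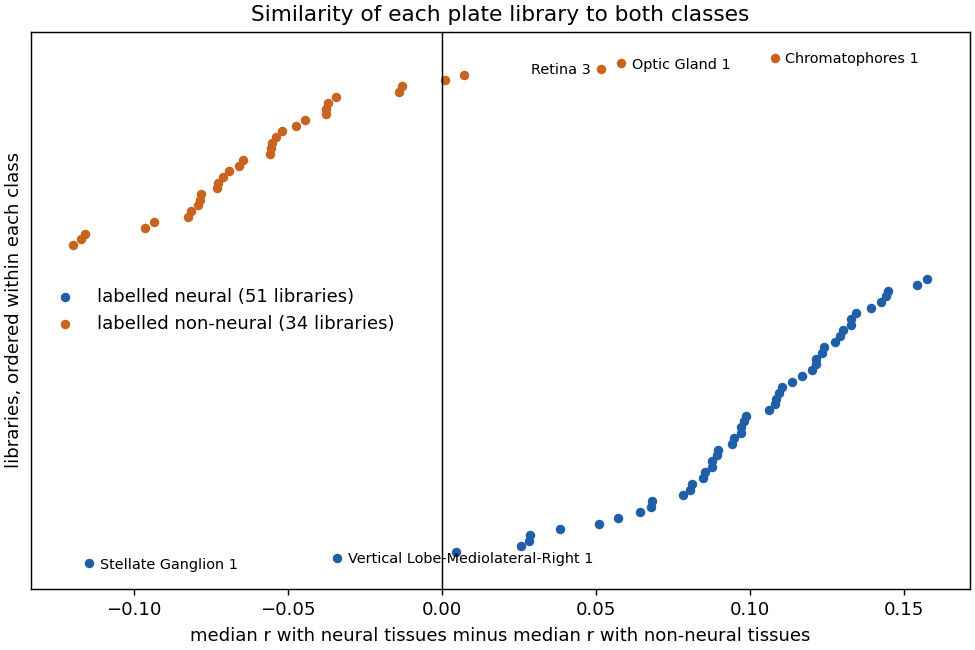
Median correlation with neural tissues minus median correlation with non-neural tissues (horizontal axis) for each of the 85 plate libraries, neural in blue and non-neural in orange, ordered within their class. The 5 libraries set apart lie on the side of the other class, as do the arm tip and the hectocotylus, both close to 0.

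In the main analysis neural tissues had more genes of higher than of lower expression. Of 15094 genes, 2872 were higher and 786 lower in the 21 neural than in the 25 non-neural tissues in limma, and 2436 of the 2872 had their highest tissue mean in a neural tissue. LOC106868274 reached a mean of 15634 ± 24280 TPM (SD, 51 libraries) against 521 ± 2210 (34 libraries), with a log2 difference of 6.55 ± 0.72 (SE) and an adjusted p of 3.4e-10 in limma, and was above 0 in all libraries of both classes. LOC106876803 averaged 2711 ± 3537 against 105 ± 535 TPM (log2 difference 6.61 ± 0.50, adjusted p 1.9e-14 in limma). In the library labelled chromatophores 1 LOC106868274 and LOC106876803 stood at 12859 and 3133 TPM, and in that labelled stellate ganglion 1 at 11.6 and 5.75 TPM; without chromatophores 1 their non-neural means were 147 and 12.8 TPM. LOC106870694 was lower in neural tissue, at 17.998 ± 60.95 against 141 ± 178 TPM (log2 difference -3.59 ± 0.52, adjusted p 3.0e-07 in limma), and was above 0 in 41 of 51 neural and all 34 non-neural libraries; its highest neural value, 399 TPM, was in the library labelled right mediolateral vertical lobe 1. LOC106870695 was lower as well (115 ± 593 against 634 ± 980 TPM, log2 difference -3.65 ± 0.69, adjusted p 4.3e-05 in limma, above 0 in 46 of 51 and 33 of 34 libraries). The same library held 4195 TPM of it, without which the neural mean was 32.95 TPM. Its call ended within the label style that starts with a 4-digit number (adjusted p 0.102 in limma). Genes lower in neural tissue most often peaked in ova (113), skin (88), gill (84) or the large sucker (77).

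The direction of this split depended on the scaling. With quantile scaling 1566 genes were higher and 1446 lower, and with median ratio scaling 1323 were higher and 1849 lower; the median difference of all genes was 0.15 in the main analysis, -0.06 and -0.16. On the deposited scale 2009 genes were called, 58.2% of them higher in neural tissue. Within the 4-digit label style, the only one with many libraries of both classes, 1634 were called, and without the 5 libraries set apart 4167.

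Several sequences named as peptides or secreted proteins were higher in neural tissue. VLPep3 averaged 482 ± 1821 against 5.24 ± 15.3 TPM (log2 difference 3.47 ± 0.77, adjusted p 0.000377 in limma) and was above 0 in 28 of 51 neural and 19 of 34 non-neural libraries. GNRH, the gonadotropin-releasing hormone type peptide, averaged 58.6 ± 193 against 1.63 ± 5.21 TPM (2.18 ± 0.63, adjusted p 0.00621 in limma; above 0 in 25 and 10 libraries). Betsin (2.56 ± 0.53, adjusted p 0.000166, above 0 in 26 and 9), Sp12 (3.30 ± 0.42, adjusted p 1.9e-08, 45 and 18) and Sp38 (2.76 ± 0.68, adjusted p 0.00123, 40 and 25) were also higher in limma. IRELamide2 passed too (1.36 ± 0.29, adjusted p 0.000183 in limma, 28 and 5), though its difference was 0.90 on the deposited scale, 0.96 within the 4-digit label style and 0.99 with subdivisions merged, under the threshold of 1. APGW, the precursor of the molluscan neuropeptide APGWamide, and Insulin1, an insulin-like sequence, did not pass (differences of 0.74 and 1.22 ± 0.69, adjusted p 0.391 and 0.185 in limma), and their high values stood in few tissues. Another 9 of the 18 named sequences, among them nitric oxide synthase and 3 acetylcholine-binding proteins, were listed at 0 in all 85 plate libraries. The deepest held 13464000 reads. Whether reads could be assigned to these sequences was not tested, so this does not show absence. Expression was uneven between libraries of a region. The highest VLPep3 value, 12790 TPM, came from 1 superior buccal library, and 3 GNRH reads, the floor used here, were worth 0.939 to 297 TPM, so a listed 0 in a shallow library does not show absence.

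**Figure D3:**
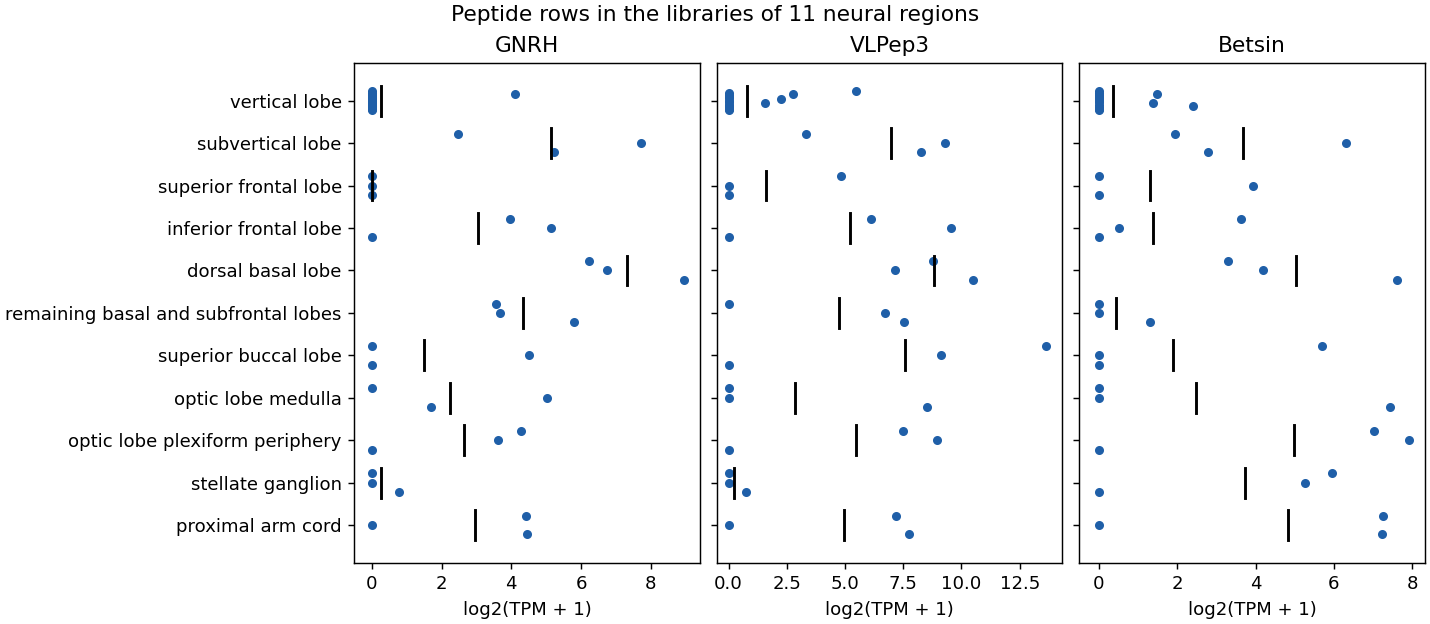
GNRH, VLPep3 and Betsin as log2(TPM + 1) (horizontal axes) in the libraries of 11 neural regions, with a point per library and a black bar at the mean of the log2 values. GNRH was above 0 in 1 of 15 vertical lobe libraries and in all 3 of the dorsal basal lobe.

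The vertical lobe was compared with the mean of the 6 other central lobes. It expressed LOC106873486 at 1315 ± 1463 TPM (SD, 15 libraries) against 157 ± 205 (18 libraries), above 0 in all 33 libraries (log2 difference 3.78 ± 0.61, adjusted p 8.0e-05 in limma), and LOC106881837 at 342 ± 292 against 45.8 ± 73.2 TPM, above 0 in 15 of 15 and 13 of 18 libraries (4.09 ± 0.76, adjusted p 0.000491 in limma). LOC106869081 was at 69.7 ± 192 TPM (20.7 without left lateral 1) against 3148 ± 6912 in the other lobes (-4.77 ± 0.74, adjusted p 4.4e-05 in limma) and LOC106875923 at 5.44 ± 7.47 against 512 ± 946 (-4.36 ± 0.76, adjusted p 0.000233 in limma). The peptides VLPep3 and GNRH were low in these 15 libraries of vertical lobe subdivisions, while both whole vertical lobe libraries of the second table held GNRH at 215 and 1494 TPM and VLPep3 at 718 and 1357 TPM. VLPep3 averaged 3.69 ± 11.2 against 970.4 ± 2974 TPM (-5.02 ± 1.11, adjusted p 0.00367 in limma, above 0 in 4 of 15 and 13 of 18 libraries; 275 TPM in the other lobes without superior buccal 3), and GNRH 1.07 ± 4.16 against 59.9 ± 121 TPM (-3.28 ± 0.62, adjusted p 0.000530 in limma, above 0 in 1 of 15 and 12 of 18). The superior frontal lobe, 1 of these 6, was low too, with GNRH listed at 0 in all 3 libraries and VLPep3 at 9.01 ± 15.6 TPM, above 0 in 1 of 3. In all, 294 genes were higher and 289 lower in the vertical lobe among 13755. The share higher was 50.4%, but 40.9% with quantile and 29.6% with median ratio scaling, which moved the median difference of all genes from 0.03 to -0.12. Within the ObRNA label style (9 vertical lobe and 7 other libraries) 2 genes passed, none of them these 6. Of the 583 genes, chosen partly on these libraries, 577 kept direction. The deposited scale gave 357 genes, and leaving out the libraries set apart, here those labelled right mediolateral vertical lobe 1 and stellate ganglion 1, gave 894. Without the former alone the count was 831.

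**Figure D4:**
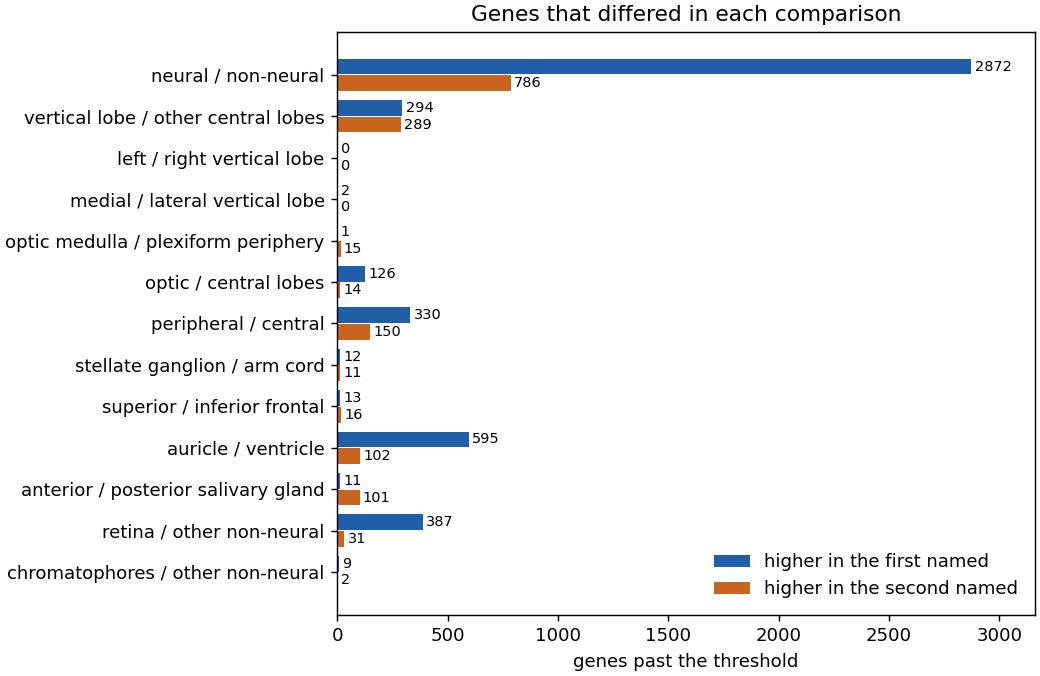
Genes past the threshold in each comparison (horizontal axis, bars from 0, counts printed), blue for higher in the tissue named first and orange for higher in that named second. The largest counts are 2872 and 786 for neural against non-neural tissues, and left against right vertical lobe has 0.

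Within the vertical lobe few differences were found. No gene differed between left and right parts in limma (6 libraries a side; 471 genes at an unadjusted p under 0.05, smallest adjusted p 0.0784), nor with voom (252 at an unadjusted p under 0.05). Leaving out right mediolateral 2 gave 6 genes, left lateral 1 gave 2, left lateral 3 or left mediolateral 3 gave 3, and superior buccal 2 or 3 gave 1, as did a pseudocount of 2 and the set without libraries under 200000 reads. In simulated data this comparison recovered 24% of 4-fold and 64% of 8-fold changes (50 genes each, 13664 genes), so most 4-fold changes would have been missed. Between the medial and lateral parts, 2 genes were higher in the medial part. LOC106881497 was at 10.1 ± 8.35 TPM in 3 medial libraries (0.749 to 16.8) and listed at 0 in all 6 lateral ones (adjusted p 0.000943 in limma; 1.00 with voom). LOC106880529 was at 5.75 ± 1.81 against 0.155 ± 0.354 TPM, with all 3 medial libraries above all 6 lateral ones (log2 difference 2.55 ± 0.48, adjusted p 0.0303 in limma). The latter call ended in limma without medial 1, 2 or 3 (adjusted p 0.254, 0.174 and 0.0743), right lateral 2 or 3 (0.120 and 0.123), or left lateral 2 or 3 (0.0817 and 0.0543), and under 6 other alternatives (0.0805 to 1.00). The count was 1 without medial 1, 4 without medial 2, 0 without medial 3, 4 without left lateral 1, 1 without left lateral 2, right lateral 2 or 3, or superior frontal 2, 1 with a pseudocount of 0.5, median ratio scaling or the deposited scale, and 0 with voom (71 at an unadjusted p under 0.05), a 5 TPM filter (198) or a fit on these tissues alone (120).

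In the optic lobe, the deep medulla expressed LOC106867875 at 429 ± 161 TPM (SD, n = 3) against 6.65 ± 8.13 in the plexiform periphery (2.11 without periphery 3), and the periphery expressed LOC106880513, also the leading gene of the retina, at 1036 ± 914 TPM against 6.08 ± 5.75. Both separated all 3 libraries from all 3 (log2 differences 6.54 ± 1.42 and -7.16 ± 1.44, adjusted p 0.0381 and 0.0163 in limma). The former call ended in limma without any 1 of 5 libraries, periphery 1 or 2 (adjusted p 0.267 and 0.0924) or medulla 1, 2 or 3 (0.226, 0.134 and 0.0604), and the latter without periphery 1 or 3 (0.108 and 0.0655) or medulla 2 (0.222). Other alternatives ended them too, 5 for LOC106867875 (adjusted p 0.0554 to 0.255 in limma) and 3 for LOC106880513 (0.0762 to 0.461). LOC106875478 was also higher in the periphery, at 177 ± 84.6 against 25.4 ± 44.1 TPM, above 0 in 3 of 3 periphery libraries and in medulla 3 alone (log2 difference -5.24 ± 1.15, adjusted p 0.0452 in limma). Its call ended in 36 of 61 alternatives. Of these, 30 left out 1 library and 6 were others (adjusted p 0.0569 to 1.00 in limma). Among the 30 were medulla 1 and 2 (0.596 and 0.446) and periphery 2 and 3 (0.168 and 0.152). The rest, at 0.0503 to 0.0584, were left lateral, left and right mediolateral, superior buccal and superior frontal 1, 2 and 3, medial and subvertical 1 and 3, remaining basal and stellate ganglion 2 and 3, right lateral 2, dorsal basal 1 and arm cord 3. In all, 1 gene was higher in the medulla and 15 in the periphery; 31 passed without medulla 3, 29 with no filter, 26 with a pseudocount of 2, 26 with quantile scaling (19.2% higher in the medulla against 6.25%, with the median of all genes at 0.03 against -0.11), and none with voom (364 at an unadjusted p under 0.05) or in a fit on these tissues alone (218). Medulla libraries had a median of 229828 reads and periphery libraries 1819640.

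Together, both optic lobe parts differed from the central lobes mainly by genes that were higher. LOC106874385 was above 0 in 6 of 6 optic lobe libraries and in 3 of 33 central ones, at 104 ± 157 against 0.268 ± 0.957 TPM (log2 difference 5.28 ± 0.39, adjusted p 1.2e-12 in limma). LOC106871860 averaged 3938 ± 3637 against 779.6 ± 2202 TPM (5.32 ± 0.93, adjusted p 0.000449 in limma, above 0 in 6 of 6 and 27 of 33). LOC106874957 was lower, at 10.2 ± 12.0 against 2189 ± 6012 TPM (-4.65 ± 0.99, adjusted p 0.00560 in limma, above 0 in 5 of 6 and 32 of 33; adjusted p 0.116 with voom). LOC106878214 was lower as well, at 28.7 ± 69.9 (0.180 without medulla 3) against 307 ± 451 TPM (-4.85 ± 1.06, adjusted p 0.00766 in limma, above 0 in 2 of 6 and 33 of 33). That call ended without medulla 1 or 2 (adjusted p 0.0682 and 0.0576 in limma), on the deposited scale (0.238) and with voom (0.0840). In all, 126 genes were higher and 14 lower, and 50 and 24 of the 126 had their highest tissue mean in the periphery and the medulla. On the deposited scale 73 genes passed. Quantile scaling moved the median difference of all genes from 0.12 to -0.03. Most central but no optic lobe or peripheral libraries have the ObRNA or ObA label style, so in neither comparison was tissue separated from style.

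Peripheral nervous tissue, the stellate ganglion and arm cord, had 330 genes higher and 150 lower than the central lobes. LOC106871334, the leading vertical lobe gene, was at 1.05 ± 1.36 TPM in 6 peripheral against 285 ± 364 in 33 central libraries (log2 difference -4.66 ± 0.60, adjusted p 2.9e-06 in limma), and LOC106876030 at 11.1 ± 15.5 against 637 ± 659 (-5.48 ± 0.94, adjusted p 0.000242 in limma; above 0 in 4 of 6 and 32 of 33). LOC106880211 was higher, at 174 ± 202 against 1.52 ± 5.59 TPM (5.46 ± 0.65, adjusted p 1.6e-06 in limma, above 0 in 6 of 6 and 13 of 33). It stood at 540 and 252 TPM in stellate ganglion 2 and 3 but at 1.62 in the library labelled stellate ganglion 1. LOC106884243 (2440 ± 4264 against 79.4 ± 218 TPM, 5.13 ± 0.87, adjusted p 0.000217 in limma) went the other way, with 11060 TPM in the library labelled stellate ganglion 1 (peripheral mean 717 without it) against 158 and 182, and 3380 TPM in chromatophores 2. Of the 330 higher genes, 64 had their highest tissue mean in neural tissue, and skin (31) and the clear vessel of the systemic heart (30) were the most frequent top tissues. Leaving out the library labelled stellate ganglion 1 gave 316 genes and leaving out arm cord 3 gave 298; voom gave 1332, with 54.9% higher against 68.8%, log10 reads as a covariate 724, and the set without libraries under 200000 reads 793. The median difference of all genes was -0.16, and -0.06 with median ratio scaling.

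Between those tissues, 12 genes were higher in the stellate ganglion and 11 in the arm cord. LOC106870130 was at 293 ± 157 TPM in the arm cord and 3.87 ± 5.43 in the stellate ganglion (log2 difference -6.42 ± 1.24, adjusted p 0.0115 in limma), and LOC106882120 at 101 ± 50.1 against 0.0779 ± 0.135 (-6.42 ± 1.34, adjusted p 0.0201 in limma), all 3 libraries above all 3 for both. LOC106882236 (548 ± 761 against 0.315 ± 0.472 TPM, 7.66 ± 1.58, adjusted p 0.0199 in limma) and LOC106869698 (591 ± 585 against 2.12 ± 3.43, 7.62 ± 1.68, adjusted p 0.0371 in limma) were higher in all 3 stellate libraries. The library labelled stellate ganglion 1 held most of that, at 1426 TPM against 122 and 95.1, and 1254 against 369 and 149. LOC106869698 also stood at 1670 TPM in chromatophores 2 and 1975 in the library labelled right mediolateral vertical lobe 1. Without stellate ganglion 1 the adjusted p in limma was 0.117 for LOC106882236 and 0.131 for LOC106869698, and without stellate ganglion 2 that of LOC106869698 was 0.0928. Without the libraries set apart the adjusted p in limma was 0.0874 for LOC106882236 and 0.0507 for LOC106869698. LOC106882236 also lost its call without arm cord 1, 2 or 3 (0.0798, 0.0709, 0.0910), as did LOC106869698 (0.0796, 0.156, 0.166). LOC106870130 lost it without arm cord 1 or 3 or stellate ganglion 2 (0.101, 0.0651, 0.0812), as did LOC106882120 (0.156, 0.109, 0.0642). A fit on both tissues alone ended all 4 (adjusted p 0.104 to 0.207), the deposited scale LOC106870130 (0.0598) and LOC106882120 (0.102), and a pseudocount of 0.5 LOC106869698 (0.0681). The count was 42 without stellate ganglion 1, 43 without stellate ganglion 3, 46 without the library labelled right mediolateral vertical lobe 1, 5 without arm cord 1, 12 without arm cord 3, 45 with quantile scaling, 65 with voom or without libraries under 200000 reads, 54 without the libraries set apart, 37 with no filter, 14 with a filter of 5 TPM, and 0 in a fit on both tissues alone (297 at an unadjusted p under 0.05). Quantile scaling moved the median difference of all genes from -0.07 to 0.05.

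The superior and inferior frontal lobes, brain lobes on the visual and the tactile side of learning, differed in 13 genes higher in the superior and 16 in the inferior lobe. LOC106880020 was at 11819 ± 7509 TPM in the inferior and 68.3 ± 28.6 in the superior lobe (log2 difference -7.19 ± 1.03, adjusted p 0.000142 in limma), every inferior library above every superior one, and it kept its call under each of 61 alternatives. LOC106876168 was at 596 ± 682 against 4.77 ± 8.26 TPM (-7.11 ± 1.36, adjusted p 0.00709 in limma). LOC106869803 was at 896 ± 526 TPM in the superior lobe against 8.34 ± 14.4, all of it from inferior 2 (8.02 ± 1.71, adjusted p 0.0214 in limma), and LOC106884341 at 248 ± 167 TPM while listed at 0 in all 3 inferior libraries (adjusted p 0.00709 in limma). These 3 separated all 3 libraries from all 3 but lost their calls when a library was left out. In limma, the adjusted p of LOC106869803 was 0.0695, 0.121 and 0.0648 without superior 1, 2 or 3 and 0.166 and 0.164 without inferior 1 or 3. That of LOC106884341 was 0.0899 and 0.0659 without superior 2 or 3, and that of LOC106876168 was 0.101 and 0.0877 without superior 2 or 3 and 0.108 without inferior 2. A fit on both lobes alone (adjusted p 0.115 to 0.239) and the set without libraries under 200000 reads (0.0585 to 0.266) ended all 3, a pseudocount of 0.5 LOC106869803 (0.0600), and the deposited scale (0.192) and voom (0.0584) LOC106876168. The count was 58, 8 and 13 without superior 1, 2 and 3 and 18, 18 and 15 without inferior 1, 2 and 3. Quantile scaling gave 44 genes, 63.6% higher in the superior lobe against 44.8% and the median of all genes at 0.06 against -0.12, a pseudocount of 0.5 gave 19, voom 18, the set without libraries under 200000 reads 11 and a fit on both lobes alone 3. All 6 libraries share the ObRNA label style.

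Each of the 11 neural regions had genes that marked it against the other 10, 886 in all. The dorsal basal lobe expressed LOC106874496 at 383628 ± 137950 TPM (SD, n = 3; 224484 to 469125), 22.4% to 46.9% of the TPM of its libraries, against 7054 ± 23803 elsewhere (log2 difference 9.45 ± 1.35, adjusted p 5.3e-05 in limma). GNRH was highest there too, at 226 ± 235 against 12.4 ± 33.99 TPM, above 0 in 3 of 3 and 17 of 42 libraries (5.07 ± 1.06, adjusted p 0.0212 in limma). That call ended in limma without dorsal basal 1, 2 or 3 (adjusted p 0.464, 0.0934 and 0.0616), without libraries under 200000 reads (0.0518) and with reads as a covariate (0.0762). The remaining basal and subfrontal lobes expressed LOC106874957 at 18166 ± 10799 against 648 ± 1564 TPM (7.92 ± 1.30, adjusted p 0.00106 in limma), and the superior frontal lobe LOC106871087 at 27510 ± 15136 against 1444 ± 4065 (6.09 ± 0.90, adjusted p 0.000142 in limma), with 3 of 3 libraries above the mean of the others in both. LOC106871334 marked the vertical lobe, at 528 ± 413 against 49.6 ± 95.8 TPM (4.95 ± 0.42, adjusted p 1.7e-10 in limma, above 0 in 15 of 15 and 29 of 30 libraries). The arm cord expressed LOC106878553 at 542 ± 342 against 13.8 ± 24.7 TPM (5.82 ± 0.80, adjusted p 1.3e-05 in limma; 3 of 3 libraries above all 42 others). These genes, GNRH apart, kept their calls in all 60 alternatives run for each.

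Of the 23 genes named by the rule over all regions, 11 kept their calls in every alternative and 12 did not. Among the former, LOC106880513 marked the periphery (1036 ± 914 against 6.90 ± 22.8 TPM, log2 difference 8.03 ± 1.06, adjusted p 3.2e-06 in limma), as did LOC106875478 (6.42 ± 0.85, adjusted p 3.3e-06). LOC106883198 marked the stellate ganglion (362 ± 406 against 5.60 ± 21.8 TPM, 6.99 ± 1.00, adjusted p 4.7e-05 in limma) and LOC106878234 the inferior frontal lobe (70.4 ± 10.6 against 3.52 ± 15.01 TPM, 5.46 ± 0.84, adjusted p 0.000316 in limma). LOC106870262 marked the remaining basal lobes and LOC106870414 the arm cord (6.00 ± 0.88 and 5.63 ± 0.95, adjusted p 0.000180 and 0.000308 in limma). The weakest were both genes of the superior buccal lobe, LOC106873782 (12143 ± 10648 against 243 ± 483 TPM, 5.64 ± 1.12) and LOC106871922 (11.9 ± 15.6, or 2.89 without superior buccal 3, against 0.479 ± 1.14 TPM, 2.45 ± 0.46), each at an adjusted p of 0.0378 in limma. The call of LOC106873782 ended in 31 of 60 alternatives and that of LOC106871922 in 26 of 58. Without superior buccal 2 or 3 the adjusted p in limma was 0.445 and 0.537 for the former and 0.0573 and 0.834 for the latter. Both also ended, at 0.05002 to 0.0547, without periphery, superior frontal 1, 2 or 3, remaining basal 2 or 3, subvertical or medulla 1 or 2, dorsal basal 2 or 3, left lateral 2 or 3, left mediolateral 1, or arm cord 1 or 3, and LOC106873782 also without dorsal basal 1, remaining basal 1 or stellate ganglion 2. Other alternatives ended LOC106873782 in 7 cases (0.0533 to 0.481) and LOC106871922 in 5 (0.0508 to 0.794). In the subvertical lobe LOC106871750 (20654 ± 21644 against 2092 ± 7355 TPM, 9.17 ± 1.77, adjusted p 0.0127 in limma) lost its call without subvertical 1 or 2 (0.124 and 0.230), and LOC106871752 (6.46 ± 1.08, 0.00238) without subvertical 2 (0.0623). In the medulla LOC106871860 (6269 ± 3918 against 734 ± 1995 TPM, 6.38 ± 1.22, adjusted p 0.00727 in limma) lost it without medulla 1 or 2 (0.0884 and 0.0910), and without superior buccal 1 (0.00467) because its highest mean lay in another region. LOC106882120 (4.52 ± 0.99, adjusted p 0.0261 in limma) lost it there without medulla 1, 2 or 3 (0.189, 0.0910 and 0.167), on the deposited scale (0.278), with a pseudocount of 0.5 (0.0699) and with the letter as a block (0.0736), and without periphery 1 (0.0301) because its highest mean lay in another region. Single libraries also ended LOC106869081 in the dorsal basal lobe (6.72 ± 1.28, adjusted p 0.00645 in limma; 0.197 and 0.196 without dorsal basal 1 and 3), LOC106884069 in the inferior frontal lobe (4.85 ± 0.91, 0.00548; 0.114 and 0.0517 without inferior frontal 2 and 3), LOC106869803 in the superior frontal lobe (6.81 ± 1.26, 0.00315; 0.0617 without superior frontal 2) and LOC106869698 in the stellate ganglion (6.48 ± 1.24, 0.00235; 0.0541 without the library labelled stellate ganglion 1). On the deposited scale the highest mean of LOC106881837 (4.47 ± 0.69, adjusted p 1.7e-05 in limma; 9.8e-05 there) lay outside the vertical lobe.

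The sets differed in how far they held beyond the nervous system. Over all 46 tissues, 38 of 50 superior frontal and 48 of 96 periphery genes still had their highest mean in that region, and 12 periphery genes had it in the retina. Of 125 stellate ganglion genes 9 did, while 22 peaked in gill, 15 in the large sucker and 13 in skin; this set includes the library labelled stellate ganglion 1. The vertical lobe set held 369 genes, 609 without the library labelled right mediolateral vertical lobe 1. It rests on 15 libraries and each other region on 3, so its count cannot be set against theirs as a measure of distinctness. In simulated data 88% of 4-fold changes were recovered for the vertical lobe (25 genes, 13681 tested). For the stellate ganglion 4% were (25 genes, 13729 tested). The arm cord count of 139 was 70 and 82 without arm cord 1 and 3, and that of the stellate ganglion 70, 218 and 223 without stellate ganglion 1, 2 and 3. The periphery had 53 genes without periphery 2, and the superior frontal lobe 12 and 16 without superior frontal 2 and 3. The medulla had 33 genes and 12 without medulla 1. The inferior frontal lobe had 26, against 49 without the library labelled stellate ganglion 1, 15 without inferior frontal 2 and 10 without 3. The subvertical lobe had 21, and 11, 4 and 57 without subvertical 1, 2 and 3. The dorsal basal lobe had 15 and 7 without dorsal basal 1, and the remaining basal lobes 8 and 13 without their library 2. The superior buccal lobe had 4, and 21 and 2 without superior buccal 1 and 3, 2 without dorsal basal 1 or remaining basal 1, 1 without stellate ganglion 2, and 0 by limma without any 1 of the libraries of other regions that ended both its named genes (768 to 990 at an unadjusted p under 0.05). Its count was also 0 with a pseudocount of 0.5 (911 at an unadjusted p under 0.05), no filter (914), a filter of 5 TPM (791), the deposited scale (675) and reads as a covariate (593), 1 with voom or without the libraries set apart, and 2 without libraries under 200000 reads. Scaling moved the counts as well. Median ratio scaling gave 216 vertical lobe and 54 dorsal basal genes, and quantile scaling 271 stellate, 39 dorsal basal, 18 remaining basal, 11 superior buccal and 9 subvertical genes. On the deposited scale there were 215 vertical lobe, 70 subvertical, 23 dorsal basal, 10 inferior frontal and 6 medulla genes. Voom called 1609 genes in all, among them 576 for the vertical lobe, 433 for the stellate ganglion, 257 for the arm cord, 71 for the inferior frontal, 50 for the subvertical and 29 for the dorsal basal lobe, and 13 for the medulla. Without libraries under 200000 reads the vertical lobe had 732 genes, the stellate ganglion 191 and the superior frontal lobe 17. Without the libraries set apart the vertical lobe had 607, the arm cord 225, the inferior frontal lobe 55 and the subvertical lobe 34. With reads as a covariate the vertical lobe had 597, the inferior frontal lobe 40, the subvertical lobe 13 and the dorsal basal lobe 9. A filter of 5 TPM gave 18 medulla, 14 inferior frontal, 8 dorsal basal and 4 remaining basal genes, and a pseudocount of 0.5 gave 19 medulla genes.

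The auricle and ventricle of the branchial heart, which pump blood through the gills, differed in 595 genes higher in the auricle and 102 in the ventricle. LOC106870155 was at 1863 ± 687 TPM in the auricle and 3.34 ± 1.80 in the ventricle (SD, n = 3 each; log2 difference 8.77 ± 1.71, adjusted p 0.00519 in limma), and LOC106882236 at 2520 ± 1697 against 4.71 ± 3.23 (8.65 ± 0.89, adjusted p 0.000225 in limma). LOC106882321 reached 4296 ± 2083 TPM in the ventricle against 7.23 ± 10.2 (1.39 without auricle 3; -9.81 ± 1.18, adjusted p 0.000379 in limma), and LOC106868627 4409 ± 6128 (876 without ventricle 2) against 5.28 ± 2.37 (-8.35 ± 1.13, adjusted p 0.000574 in limma). All 4 separated every library of both parts. Betsin was higher in the auricle as well, at 39.2 ± 43.6 against 0.253 ± 0.438 TPM, in 3 of 3 libraries (4.39 ± 0.85, adjusted p 0.00483 in limma; 0.0531 in a fit on both parts alone). Of the 102 ventricle genes 70 had their highest tissue mean there. The 595 auricle genes most often peaked in the male gonad (193), the auricle (73), the clear vessel of the systemic heart (64) or gill (60), and 56 peaked in neural tissue. Auricle 2 lay nearest to the male gonad (r = 0.846), above its correlations with auricle 1 and 3 (0.796 and 0.685); without it 479 genes were higher in the auricle, and 153 of them peaked in the male gonad. Without ventricle 1 the count was 405. All 6 libraries share the 4-digit label style. Other comparisons, apart from those for which values within a style are given, were not fitted within a style. The median difference of all genes was 0.14 and moved to -0.13 with quantile scaling.

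The posterior salivary gland stood out by a few genes of very high expression. LOC106882666 averaged 77517 ± 58887 TPM and LOC106879125 52196 ± 4889 TPM in 2 libraries, against 0.203 ± 0.097 and 0.350 ± 0.167 in the anterior gland (log2 differences -15.73 ± 1.92 and -15.24 ± 2.21, adjusted p 0.000160 and 0.000844 in limma; both posterior libraries above both anterior ones). The anterior gland was higher in LOC106878500 (1133 ± 222 against 1.61 ± 2.28 TPM, 9.09 ± 1.1005, adjusted p 0.000152 in limma) and LOC106877281 (2903 ± 158 against 7.79 ± 11.0, 9.48 ± 1.62, adjusted p 0.00458 in limma), in 2 of 2 libraries. The call of LOC106877281 ended in limma without anterior 1 or 2 (adjusted p 0.0646 and 0.0761) or posterior 1 (0.177). In all, 101 genes were higher in the posterior and 11 in the anterior gland, and 84 of the 101 peaked in the posterior gland over all tissues. The share higher in the anterior gland, 9.82%, was 25.7% with quantile scaling (175 genes) and 23.0% with median ratio scaling (178), and the median of all genes, -0.18, was 0.09 with quantile scaling. Leaving out posterior 1 or 2 gave 67 and 69 genes, with the lone library assumed to vary like the other tissues. Among genes of the 101 with a biotype, 11 of 94 were long non-coding RNAs, 11.7% against 4.13% of the genes tested (Fisher's exact p 0.00167, adjusted over 30 such tests 0.04995, a test chosen after the data were seen).

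The retina was compared with the other replicated non-neural tissues. LOC106880513 was at 23432 ± 14504 TPM in 3 retina libraries and 2.09 ± 2.54 in 12 others (log2 difference 13.25 ± 0.72, adjusted p 3.2e-08 in limma), and LOC106881766 at 9168 ± 6713 against 1.70 ± 2.45 (11.95 ± 0.61, adjusted p 3.2e-08 in limma). Every retina library lay above every other, and the library labelled retina 3 held the highest values, 39219 and 16579 TPM. LOC106871079 was lower, at 1.20 ± 2.07 against 116 ± 126 TPM (-5.01 ± 0.94, adjusted p 0.00602 in limma, above 0 in 1 of 3 and 12 of 12 libraries), in the main analysis and all 35 alternatives. LOC106880807 was lower too, at 28.9 ± 45.3 (2.82 without retina 2) against 11746 ± 33439 TPM (2159 without anterior salivary gland 2, at 117205; -4.93 ± 1.24, adjusted p 0.0418 in limma, above 0 in 2 of 3 and 12 of 12), but its call ended in 19 of 35 alternatives. In limma these were the sets without retina 1 or 3 (adjusted p 0.142 and 0.240), auricle 1 or 3 (0.0728 and 0.0597), ventricle 1 or 2 (0.0631 and 0.0559), anterior salivary gland 2 (0.0848), posterior salivary gland 1 or 2 (0.0750 and 0.0723) or chromatophores 2 (0.0689), and 9 others (0.0585 to 0.324), among them the sets without the anterior (0.324) or the posterior salivary gland (0.206) as a tissue. Sp12 was higher, at 32.7 ± 15.3 against 2.39 ± 3.20 TPM (3.69 ± 0.81, adjusted p 0.0191 in limma, in 3 of 3 libraries), but not without retina 1 or 3 (adjusted p 0.0907 and 0.0505 in limma) or the ventricle as a tissue (0.0824), nor with quantile (0.0793), median ratio (0.105) or the deposited scaling (0.141), reads as a covariate (0.0544), or without libraries under 200000 reads (0.0505). In all, 387 genes were higher and 31 lower. Over all tissues 151 of the 387 peaked in the retina and 126 in neural tissue, which this comparison leaves out. The share higher was 92.6%, 73.7% with median ratio scaling, which moved the median of all genes from 0.12 to -0.31. The count was 153 on the deposited scale, 996 with voom and 1576 with reads as a covariate. It was 761 without the library labelled chromatophores 1, 914 without both chromatophore libraries, 223 and 233 without the anterior and the posterior salivary gland, 274 without anterior salivary gland 2 and 269 without posterior salivary gland 1. Retina libraries had a median of 477744 reads against 2652800. In simulated data without true change in those genes (12737 tested), 97 were called and 93 of them as lower in the retina, the direction of the 31 lower calls.

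Chromatophores, the pigment organs of the skin worked by muscles, differed from the other tissues in 9 genes higher and 2 lower, the 4 named here all at an adjusted p of 0.0450 in limma. LOC106872798 was at 317 and 328 TPM in the 2 libraries against 170 ± 310 in 13 (log2 difference 4.32 ± 0.74), and LOC106874643 at 6.37 ± 0.368 against 0.247 ± 0.486 (2.67 ± 0.45). Both libraries lay above all 13 others for LOC106874643, while LOC106872798 reached 924 TPM in another tissue. LOC106875189 was at 12.3 ± 0.809 against 74007 ± 177209 TPM (-7.78 ± 1.24), and LOC106884385 at 0.844 ± 1.19 against 402 ± 527 (-4.63 ± 0.74). LOC106875189 reached 537773 TPM in anterior salivary gland 2. The libraries labelled chromatophores 1 and chromatophores 2 correlated at only 0.668, and 8 of the 9 higher genes had their highest tissue mean in neural tissue. The median difference of all genes was 0.88, and 0.04 with quantile scaling. The calls did not hold: leaving out either library of anterior or posterior salivary gland, auricle 2 or 3, ventricle 1 or 3, or retina 1 or 3 gave 0 genes by limma, auricle 1 or retina 2 gave 1, and ventricle 2 gave 2. The main analysis had 2078 genes at an unadjusted p under 0.05 and voom called 48 genes. Without the library labelled chromatophores 1 there were 215 genes and without chromatophores 2 383, with the lone library assumed to vary like the other tissues. The count was 24 with no filter, 20 with reads as a covariate, 19 on the deposited scale, 6 with a pseudocount of 2, 1 with median ratio scaling, and 0 with a pseudocount of 0.5 (1985 at an unadjusted p under 0.05), a filter of 5 TPM (1749), quantile scaling (762), robust variance estimation (2047) or without libraries under 200000 reads (2356).

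Over all 46 tissues, 1400 of 17545 genes were specific to 1 tissue, 109 of them to a neural and 1291 to a non-neural tissue. Ova had 443 such genes, the male gonad 236, the small sucker 94, the retina 62 and the posterior salivary gland 58. Specific genes took 25.6% of the TPM in the esophagus, 12.4% in the posterior salivary gland and 7.61% in the retina. Among neural tissues the olfactory lobe (19), the optic lobe periphery (15) and the middle subesophageal lobe (15) had the most, and chromatophores had none at a tau of 0.9. Of the 1400 genes, 1182 had their top tissue among the 25 tissues with a single library, which have no replicate check. Merging subdivisions gave 1201 genes over 34 tissues, and a tau of 0.8 gave 2767.

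**Figure D5:**
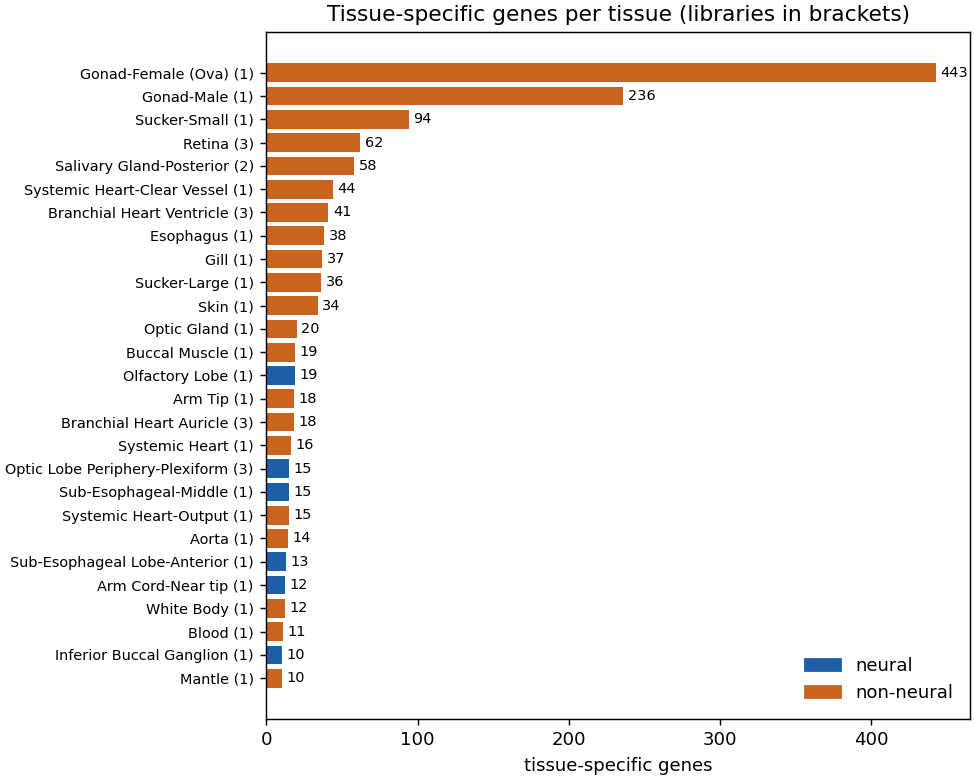
Genes specific to a tissue (tau of 0.9 or more and at least 10 TPM in the top tissue, horizontal axis, bars from 0) by tissue. Ova (443) and the male gonad (236) have the most, and neural tissues at most 19.

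Tissues with 1 library are reported by their values, with no error. The posterior subesophageal lobe held Insulin1 at 11427 TPM and GNRH at 1203 TPM, the anterior part VLPep3 at 1489 and GNRH at 527 TPM, and the middle part listed GNRH and VLPep3 at 0 and Insulin1 at 23.4 TPM, which is 2 reads. APGW was at 1748 TPM in the olfactory lobe, 927 in the library labelled optic gland and 55.8 in the inferior buccal ganglion, where VLPep3 was at 1959 TPM. The library labelled optic gland also held Sp38 at 523 and Insulin1 at 329 TPM, and the male gonad Insulin1 at 222 TPM. In the second table, IRELamide2 was at 2968 TPM in a large efferent neuron and 858 TPM in an amacrine neuron of the vertical lobe, the latter with no other named sequence at 20 TPM or more. Betsin was at 626 TPM in a stellate ganglion neuron and 401 TPM in the stellate ganglion, and Sp12 at 395 TPM in that neuron and 394 TPM in a medulla neuron. Across genes, the whole tissue libraries correlated best with a plate tissue at Spearman's rho of 0.814 to 0.909. The stellate ganglion lay nearest to the stellate ganglion (0.814), both whole vertical lobe libraries (0.892 and 0.909) and the medial superior frontal lobe (0.887) to the subvertical lobe, and the brachial ganglion to the dorsal basal lobe (0.844). The large efferent neuron correlated at 0.644 with both the right lateral vertical lobe and the subvertical lobe, and the amacrine neuron at 0.535 and 0.530 with them.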

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

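Of the tests in this part, that for exchanged labels was written before its result was seen, although its code gained a second route to exclusion afterwards. The other tests on single libraries and all counts of other splits of the samples were chosen after the results were seen.

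Spike-in RNA was present in the second table, which no comparison between groups uses, and was flagged there. It took 0.000147% of the TPM in the brachial ganglion, 0.000117% in the medial superior frontal lobe, 0.000121% in the stellate ganglion, 0.000163% in whole vertical lobe 1 and 4.82% in whole vertical lobe 2. In single neurons it took 1.28% in the medulla neuron, 0.522% in the optic periphery neuron, 0.629% in the stellate neuron, 0.0686% in the amacrine neuron and 0.244% in the large efferent neuron. No tissue has 4 to 10 libraries, so none was tested for a library far from the rest. The left minus right difference did not differ between the lateral and mediolateral vertical lobe in any gene in limma (800 genes at an unadjusted p under 0.05, smallest adjusted p 0.173; no other tool was run).

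Several libraries lay closer to the other class than to their own. In the library labelled chromatophores 1, vertical lobe tissue with some chromatophore tissue was argued against. A set of skin over vertical lobe genes had a median log2 0.555 below the highest of 14 vertical lobe libraries (difference -0.555). For an exchange with the library labelled right mediolateral vertical lobe 1, the skin set stood in that library at -0.11 on a scale with 0 at the suckers and 1 at chromatophores 2, and a sucker set stood at the level of chromatophores 2; neither bound set beforehand was met, so the exchange may or may not have happened. Skin or chromatophore tissue in that library stayed open as well, as 23 of 36 skin genes that would give 5 or more reads had a read, with 1622 reads against 25507 expected, and so did a mixture of vertical lobe and another tissue there (vertical lobe set 0.809 above the highest of skin, chromatophores 2, suckers and gill) and of stellate ganglion and skin in the library labelled stellate ganglion 1 (stellate set 0.431 above the higher of skin and chromatophores 2). In the library labelled retina 3, another tissue of the plate under a wrong label was argued against. There, 50 genes highest in retina 1 and 2 stood at a median log2 7.166 above the highest of 82 libraries of other tissues. Those 82, each with its own tissue left out of the choice of genes, stood at most 0.645 above the rest. A mixture with another tissue was not tested. A single wrong label, or a swap with a sample outside the series, stays open for the other 4 libraries, and no biological explanation was tested.

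Other splits of the same libraries, the real one counted, gave as many genes in 1 of 100 for neural against non-neural tissue (3658 genes, highest other 562), 1 of 100 for the vertical lobe (583, highest other 72), 4 of 100 for the optic lobes (140, 598), 1 of 100 for peripheral tissue (480, 89), 2 of 100 for region-enriched genes (886, 1268) and 3 of 100 for the retina (418, 2408). Each of these shares lay under 0.05, with no adjustment over the comparisons. They hold only if the libraries, or the tissues for neural against non-neural, are exchangeable, which the labels do not show. Chance is therefore less likely in these but not excluded. For left against right vertical lobe the count decides nothing, since any of the 100 splits gives at least the real 0 genes (highest other 275). The share was above 0.05 for medial against lateral, where 36 of 84 gave at least 2 (highest other 621). The 10 splits of 3 against 3 libraries are too few for a share under 0.05: 3 gave as many genes as medulla against periphery (16, highest other 92), 2 as stellate ganglion against arm cord (23, highest other 390), 1 as the frontal lobes (29, highest other 15) and 1 as the heart parts (697, highest other 1). Splits that called several times the real count, as for medial and lateral, medulla and periphery, the stellate ganglion, the optic lobes and the retina, may point to a structure of the samples other than the groups, but which libraries those splits put together was not examined.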

How the results depend on the processing

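Which alternatives were fixed before the data were seen is given above. No named gene reversed its direction. The side with most calls did change in 1 of 62 alternatives for neural against non-neural tissue (median ratio scaling, 1323 higher and 1849 lower), 35 of 63 for the vertical lobe (50.4% higher; 29.6% to 65.8%), 23 of 60 for the stellate comparison (52.2%; 13.6% to 70.4%), 6 of 61 for the frontal lobes (44.8%; 27.3% to 66.7%) and 4 of 18 for chromatophores, counting alternatives that gave calls. Of 4235 tests of named genes under the alternatives, 3907 kept the call and 328 lost it. Some lost it only because the highest mean lay in another region. No test exists for 58 second-table values. The late change of the main scale and the limit that depth sets on low values are given above. In simulated data, 4-fold changes were recovered at 2% for medulla against periphery (13693 genes), stellate ganglion against arm cord (13711) and the heart parts (12724), and 0% for the frontal lobes (13721) and salivary glands (12724), against 98% for neural against non-neural tissue (14551) and 82% for the vertical lobe (13703). The simulation drew all libraries of a fit from a shared mean profile at a dispersion of 0.4 and changed only genes at 5 TPM or more. It therefore held no differences between the tissues of a side. Those differences are the noise of the neural against non-neural test, so the 98% does not measure the power of that test. The alternatives on estimated correlation and list members were not run, since no list matched a gene. Except where fewer samples or genes were tested, the cause of the moves listed here was not tested.

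The deposited scale gave 2009 genes for neural against non-neural tissue (3658), 357 for the vertical lobe (583), 73 for the optic lobes (140), 153 for the retina (418), 19 for chromatophores (11) and 1 for medial against lateral vertical lobe (2). With voom there were 1332 genes for peripheral tissue (480), 65 for the stellate ganglion against arm cord (23), 18 for the frontal lobes (29), 996 for the retina, 48 for chromatophores, 1609 region-enriched genes (886), and 0 for medulla against periphery (16) and for medial against lateral vertical lobe. Without libraries under 200000 reads, peripheral tissue had 793 genes, the stellate comparison 65, the frontal lobes 11, left against right vertical lobe 1 (0) and chromatophores 0. Reads as a covariate gave 724 genes for peripheral tissue, 1576 for the retina and 20 for chromatophores. Without the libraries set apart, the vertical lobe had 894 genes, the stellate comparison 54 and chromatophores 214. Within the 4-digit style neural against non-neural tissue had 1634 genes, and within ObRNA the vertical lobe 2.

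Quantile scaling gave 26 genes for medulla against periphery, 45 for the stellate comparison, 44 for the frontal lobes, 175 for the salivary glands (112) and 0 for chromatophores. Median ratio scaling gave 178 for the salivary glands, 1 for medial against lateral vertical lobe and 1 for chromatophores. A pseudocount of 0.5 gave 1 gene for medial against lateral vertical lobe, 19 for the frontal lobes and 0 for chromatophores, and a pseudocount of 2 gave 1 for left against right vertical lobe, 26 for medulla against periphery and 6 for chromatophores. With no filter there were 29 genes for medulla against periphery, 37 for the stellate comparison and 24 for chromatophores, and with a filter of 5 TPM 0 for medial against lateral vertical lobe, 14 for the stellate comparison and 0 for chromatophores. Robust variance estimation gave 0 for chromatophores. Fits on the compared groups alone gave 0 for medial against lateral vertical lobe, medulla against periphery and the stellate comparison, and 3 for the frontal lobes. Without chromatophores, anterior or posterior salivary gland as a tissue, the retina had 914, 223 and 233 genes. Chromatophores had 0 without the ventricle, 2 without the retina, and 1 without the anterior or the posterior salivary gland. A tau of 0.8 gave 2767 tissue-specific genes (1400).

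For limma counts of 0, the number at an unadjusted p under 0.05 is given above. For chromatophores without the ventricle it was 2225.

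Libraries left out one at a time gave 3486 to 3847 genes for neural against non-neural tissue with each tissue left out, 474 to 831 for the vertical lobe, 0 to 6 for left against right, 0 to 4 for medial against lateral, 13 to 31 for medulla against periphery, 110 to 164 for the optic lobes, 298 to 661 for peripheral tissue, 5 to 46 for the stellate comparison, 8 to 58 for the frontal lobes, 773 to 1200 region-enriched genes, 405 to 871 for the heart parts, 67 to 117 for the salivary glands, 269 to 761 for the retina and 0 to 383 for chromatophores.

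Libraries share replicate numbers and letters across tissues. Each neural tissue of the fit holds the letters A, B and C, except the optic medulla with B, B and C. Deviations of same-numbered neural libraries correlated at a median of -0.0244 over 315 pairs, same-lettered at 0.0333, and same-numbered non-neural at -0.0739 over 33 pairs. Medians over pairs with different numbers or letters were 0.00232, -0.0146 and 0.0728. These medians show no general pairing. Single same-lettered neural pairs ranged from -0.722 to 0.817, so pairing of some libraries is not excluded. With the replicate number as a block, the vertical lobe had 586 genes, left against right 0, medial against lateral 2, medulla against periphery 16, the optic lobes 150, peripheral tissue 491, the stellate comparison 27, the frontal lobes 29, the regions 882, the heart parts 730, the salivary glands 117, the retina 379 and chromatophores 0. The letter as a block gave 620 for the vertical lobe, and averages per letter 417.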

Other observations

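Chosen after the results were seen were the tests on depth and the levels that retinal RNA would need; of the others, those on retinal cells and on neighbouring lobes were written before their own result but prompted by genes already seen.

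Single neurons differed in how many genes they held at 1 TPM or more, with 6553 in the amacrine and 9466 in the large efferent neuron of the vertical lobe, 7796 in the stellate, 13050 in the medulla and 13526 in the optic periphery neuron, against 10481 and 9645 in the whole vertical lobe libraries. In the medulla and periphery neurons nearly every gene above 0 reached 1 TPM, as 13051 and 13526 genes were above 0. The whole vertical lobe libraries had 14076 and 13261 genes above 0, so the order of these counts depends on the threshold. The shares of each class given next are not adjusted for the number of genes at 1 TPM. Of the genes higher in neural tissue, the amacrine neuron had 69.7% at that level, the large efferent neuron 86.3% and the whole vertical lobe libraries 96.9% and 96.6%, and of the genes higher in non-neural tissue these libraries had 21.5%, 36.9%, 48.5% and 40.6%. The stellate neuron had 61.7% and 39.9%, the optic periphery neuron 90.5% and 77.6%, and the medulla neuron 88.8% and 74.0%. With 1 library each these shares have no replicate check. The other 3 neurons resembled no plate tissue closely, with their best Spearman's rho across genes at 0.366 (medulla neuron, with the subvertical lobe), 0.298 (periphery neuron, subvertical lobe) and 0.309 (stellate neuron, medulla). The brachial ganglion expressed VLPep3 at 335 and Betsin at 119 TPM, and the arm cord near its tip VLPep3 at 164, Betsin at 62.4 and GNRH at 55.6 TPM. Among tissues with 1 library, the olfactory lobe lay nearest to the inferior buccal ganglion (r = 0.876), and these held VLPep3 at 1933 and 1959 TPM.

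GNRH and VLPep3 were high in the whole vertical lobe libraries, but GNRH was above 0 in 1 of 15 subdivision libraries. Lower depth of the subdivisions was argued against: in the 8 libraries where 3 GNRH reads are worth under 21.5 TPM, 10% of the lower whole library, the highest GNRH value was 16.1 TPM. A limit tried earlier, 3 reads under 1 TPM, was met by 0 libraries and replaced. Tissue of neighbouring lobes stays open: genes enriched in the subvertical and basal lobes together ranked above the vertical lobe subdivisions by a median of 11.5 and 10.079 percentile points in both whole libraries, against at most 5.51 and 4.39 for the sets of distant tissues, but the dorsal basal set (24.4 and 29.0) carried this, with the subvertical set at 8.22 and 6.63 and the remaining basal set at 6.67 and 4.33, the last below the highest distant set. The superior buccal set of 4 genes (11.1 and 12.4), not counted as a neighbour, lay above the subvertical set, as did the inferior frontal set in whole library 2 (8.16); that each set should lie above the distant ones was asked only after the pooled value had been seen. The dorsal basal set holds GNRH itself and ran from -7.17 (stellate ganglion) to 23.0 (stellate neuron) in the other second-table libraries. Both whole libraries lay nearest to the subvertical lobe, and a difference between animals or dissections stays untested.

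More genes were higher in the optic periphery than in the medulla. Retinal RNA as the source of these calls was argued against, since 2 of the 15 periphery genes peaked in the retina, 13 stood higher in the periphery than in the retina itself, and the other 2 would need 4.40% and 5.18% of their retina level. A trace of it was not excluded: 20 abundant retina genes stood at a median of 0.116% of their retina level in the periphery (0.309% in library 1 and 0 in libraries 2 and 3) against 0.00608% in the medulla (0 in each library), with 14 of the 20 higher in the periphery. Depth as the cause stays open. Of the 16 calls 15 stayed with log10 reads as a covariate, but a linear trend cannot capture reads lost at the floor. Voom on recovered reads and a fit on these tissues alone called 0. The layers hold different cells, which may account for the calls but was not tested, and the calls rest on 3 libraries a side.

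For the vertical lobe against other lobes, 576 of the 583 calls stayed with log10 reads as a covariate. Within the ObRNA label style 98.971% of them kept direction (75.6% of all genes), at a median size of 1.68 against 1.95. Its libraries helped choose them, so this cannot weigh label style. Neighbouring genes tended to share their tissue: of 181 neighbouring pairs among 1220 tissue-specific genes with a place in assembly ASM119413v2, 90 had the same top tissue, against a median of 26 and at most 47 when top tissues were permuted (p = 0.0001, the smallest 10000 permutations can give). Ova gave 29 of these pairs, the male gonad 17, the posterior salivary gland 13 and the small sucker 12, and reads shared between neighbouring gene copies were not tested.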
